A study of Mus musculus with 24 samples.

How the data were processed

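The series holds 24 RNA-seq libraries of whole mouse hypothalamus from 3 groups of 8 libraries, saline, PSD-95i and PICK1i, with the group and replicate number of each taken from its label. The protocol text gives 6 mice for saline while the labels give 8 libraries, and the difference is not explained, so all 8 were used. The mice had a mean body weight of 53 g and were housed in pairs. The labels do not say which mouse each library came from, and separate mice were assumed. Library numbers run from 1 to 24, and the pairs 1 and 2, 3 and 4 and so on each belong to one group, called consecutive numbers here, but whether they mark cage mates or shared handling is not stated.

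The deposited tables hold estimated counts per gene and per transcript, not normalised, made by the authors from 52-base paired reads. The processing notes name bcl2fastq 2.20.0, STAR, Salmon and GRCm38, and the versions of STAR and Salmon, their options, the annotation release and the use of strand are not given in the sources used here. Of the gene values, 95.7% were whole within 0.001, and transcript values summed to the gene values. The table had 45706 genes and 109617 transcripts, and 45143 gene identifiers were found in GENCODE M21, which gave positions, biotypes, transcript lengths and GC content. Counts summed to 175921466 over all libraries (4762697 to 9228843 each), while the protocol reports 2700000000 reads, and the sources do not explain the difference. A check for duplicated libraries compared 84 pairs of replicates and found 0 identical pairs.

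Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr with its minimum count of 10 (15667 genes with 99.3% of counts, and 37955 transcripts), scaled by TMM and tested by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 fit to all 24 libraries and 21 residual degrees of freedom. The comparisons were PSD-95i against saline, PICK1i against saline and PSD-95i against PICK1i. P values were adjusted by Benjamini and Hochberg over the genes or transcripts tested, with a threshold of 0.05. All tests were two-sided except the permutation test of consecutive library numbers. Assignment of reads to transcripts of a gene is itself estimated, and that error is not in the transcript test. Mitochondrial shares were compared by exact permutation over 12870 splits, and, added after the data were seen, over the 70 assignments that keep consecutive numbers together, and correlations across libraries by exact permutation. Values per library in log2 CPM used a prior count of 2.

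Gene lists (39, with 1003 entries, 4 of which had no row in the table) covered neuropeptides and energy balance, synapses, stress and metabolism, and the cell types and neighbouring tissues that a dissection could hold. They were tested by camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. Where a symbol was shared by more than 1 identifier, the one with the larger mean count was used.

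Genes named were Dlg4, Pick1, Agrp, Npy, Pomc and Cartpt in every comparison. Added to them, against saline, were the 12 higher and the 12 lower called genes with the smallest p, a mean of at least 1 CPM and a symbol that is not a clone or model name. Between the inhibitors the rule allowed 6 and 6. Where fewer than 10 genes passed, the genes with the smallest p, up to 10, were given as values. Of each list, up to 4 members with the smallest p were available for naming. Gh and Prl were named after their values were seen.

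Groups, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. These alternatives were RLE size factors, no filter, a stricter filter, the replicate number as a fixed block, library number as a covariate, 2 surrogate variables from svaseq (sva 3.50.0), DESeq2 1.42.0, limma-voom with and without sample weights, limma-voom with consecutive library numbers as a random block, a fit of only the 2 groups compared, leaving out each library, and all 28 choices of 6 of the 8 saline libraries. After the data were seen, 6 more were added, namely leaving out saline replicates 2 and 3, leaving out PICK1i replicates 1, 2, 5 and 6, leaving out all 6, an offset for a smooth trend with transcript length and GC content, length tilt as a covariate, and an estimated correlation in camera without saline replicates 2 and 3 or without the 4 PICK1i libraries.

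The procedure was tested on simulated data with the dispersions of these libraries. At a fold of 2, edgeR called 91.4% of changed genes for PSD-95i against saline, 90.4% for PICK1i against saline and 89.9% for PSD-95i against PICK1i. At 1.5-fold it called 68.9%, 70.2% and 72.7%, and at a log2 change of 0.32 it called 23.9%, 30% and 29.2%. Of all calls 3.79%, 5.07% and 8.61% were false. For transcripts changed 2-fold it called 68.2%, 69.1% and 65.6%. A shifted microglia list was recovered by camera in all 3 comparisons, with 0, 0 and 1 other lists called. The simulated genes varied independently of each other, so these rates do not cover changes that many genes share within a library. Each gene had the same dispersion in all 3 groups, so the rates do not cover a wider spread in 1 group either. The real groups differed in spread, with an SD of the mitochondrial share of 2.61 in PICK1i and 0.628 in PSD-95i. Random splits of the real libraries called up to 24, 26 and 20 lists.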

Results

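Poly(A) RNA of whole hypothalamus was measured in 24 libraries from mice with diet-induced obesity, 8 libraries each for saline, PSD-95i and PICK1i. PSD-95i is UCCB01-147 at 25 mg/kg, an inhibitor of PSD-95, the scaffold protein of excitatory synapses that Dlg4 encodes. PICK1i is mPD5 at 56 mg/kg, an inhibitor of PICK1, a PDZ domain protein that binds AMPA receptor subunits. The protocol lists the compounds and the labels list the targets, and they were matched from what is known of the compounds. Injections were daily for 5 days, and tissue was taken 2 h after the final one. Estimated counts summed to between 4762697 and 9228843 per library, with a median of 7628246. Of 45706 genes, 15667 were tested, with a biological coefficient of variation of 14.4%. Positions below are on GRCm38. CPM is the count relative to the library total, with totals scaled by TMM for group means with SD and for log2 values. Errors of log2 fold changes are standard errors derived from the quasi-likelihood F of the fit to all 24 libraries, 8 per group. The spread of all 3 groups therefore enters them.

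Pituitary hormone transcripts were abundant in saline replicates 2 and 3. Growth hormone (Gh) stood at 52240 and 31690 CPM there and at most at 41.4 CPM in the other 22 libraries. Prolactin (Prl) stood at 7954 and 4871 CPM against at most 6.12 CPM. Pomc, the precursor of melanocortins and of pituitary ACTH, stood at 13910 and 16810 CPM in these 2 libraries. The other saline libraries held 77.1 to 154 CPM of Pomc. Mitochondrially encoded transcripts made up 9.72 ± 0.82% of counts in saline, 9.68 ± 0.628% in PSD-95i and 12.3 ± 2.61% in PICK1i (SD, n = 8 each). The PICK1i mean was above the saline mean by 2.55 percentage points (two-sided exact permutation test, p = 0.0207, adjusted p = 0.031 over 3 comparisons). Over assignments that keep consecutive library numbers together, the exact permutation test gave p = 0.114 (adjusted p = 0.171), above the threshold. The PSD-95i share differed from saline by -0.0429 points (exact permutation p = 0.908). The share was largest in PICK1i replicates 1, 2, 5 and 6, at 16.61%, 13.99%, 13.47% and 13.68%. Their 95% Wilson intervals ran from 16.58 to 16.64%, 13.96 to 14.02%, 13.44 to 13.50% and 13.65 to 13.72%, for counting error only. In a principal component analysis, saline replicates 2 and 3 lay at 63.3 and 56.9 on the first component (24.1% of variance). PICK1i replicates 1, 2, 5 and 6 lay at 25.2 to 43.0 on the second (17.1%).

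**Figure D1:**
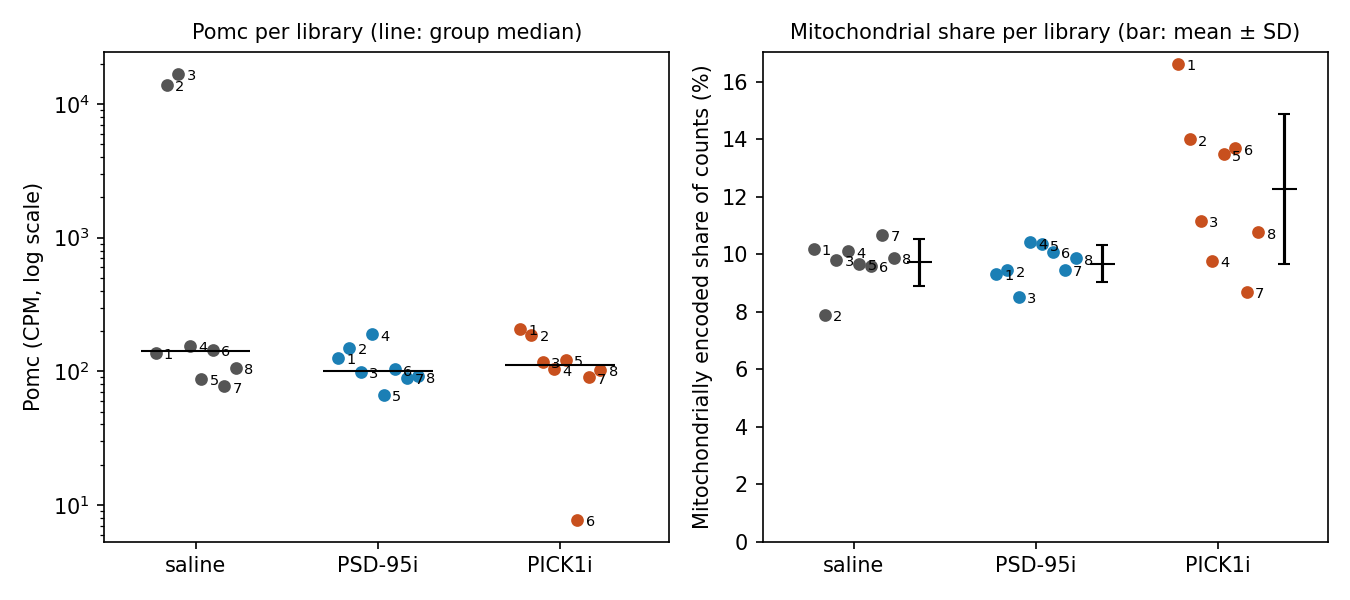
Left, Pomc in CPM on a log axis for each of the 24 libraries, with a line at each group's median; right, the mitochondrially encoded share of counts in percent for each library, with bars for the group mean ± SD (n = 8). Numbers are replicates; saline 2 and 3 lie at 13910 and 16810 CPM of Pomc, PICK1i 6 at 7.77 CPM, and the PICK1i share has a mean of 12.3%.

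The comparison of PICK1i with saline asked which transcripts differ in the hypothalamus after PICK1 inhibition. The list of 74 nuclear-encoded oxidative phosphorylation genes was higher in PICK1i, with a median log2 fold change of 0.30 (camera adjusted p = 8.63e-31, and adjusted p = 0.511 with an estimated correlation). Its mean deviation was 0.27 to 0.381 in PICK1i replicates 1, 2, 5 and 6 and -0.0767 to 0.0569 in the other 4, against -0.301 to 0.00835 in saline. Within PICK1i it was correlated with length tilt, a library's slope of log2 deviations on log2 transcript length over the other genes (r = -0.989, n = 8, exact permutation p = 0.000124). Esrra, a nuclear receptor that controls genes of oxidative metabolism, rose by 0.47 ± 0.07 on the log2 scale (37.7 ± 5.8 CPM against 27.1 ± 1.93 CPM, SD, n = 8 each, 8 of 8 libraries above the saline median, edgeR adjusted p = 0.00636). The neurofilament heavy chain gene Nefh rose by 0.42 ± 0.07 (106 ± 10.3 CPM against 79.4 ± 8.62 CPM, SD, 8 of 8 libraries, adjusted p = 0.00636). Polr3b, a subunit of RNA polymerase III, fell by 0.45 ± 0.08 (19.3 ± 2.7 CPM against 26.5 ± 2.84 CPM, SD, 8 of 8 libraries, adjusted p = 0.0112). In all, 765 genes were higher and 669 lower, 1434 of 15667 tested. Their median absolute log2 fold change was 0.34, and 91 of them differed by more than 2-fold.

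Among the 12 higher genes with the smallest p were Uncx, a homeodomain transcription factor (0.85 ± 0.14), and Ndufaf6, an assembly factor of respiratory complex I (0.66 ± 0.11), both with adjusted p = 0.00995. Atad3a, a mitochondrial inner membrane ATPase (0.38 ± 0.07), and Tomm40, the import channel of the outer mitochondrial membrane (0.33 ± 0.06), rose with adjusted p = 0.0123 and 0.0143. Unc119 (0.49), Nkiras1 (0.37), the complex I subunit gene Ndufs5 (0.46), the cytochrome oxidase subunit gene Cox5b (0.43), the heat shock transcription factor gene Hsf4 (0.43) and the histone acetyltransferase gene Kat2a (0.31) completed them. All 12 were above the saline median in at least 7 of 8 libraries. The 12 lower genes included Smad5, a mediator of BMP signals (-0.41), Wasf2, a regulator of actin (-0.34), Prelp, a matrix proteoglycan (-0.58), Atl3, a protein of the endoplasmic reticulum (-0.39), and Mpeg1, a macrophage pore-forming protein (-0.45). Sft2d2 (-0.58), Klhl24 (-0.36), Snw1 (-0.29) and Pofut1 (-0.22) fell as well, and all 9 were below the saline median in at least 7 of 8 libraries with adjusted p between 0.0151 and 0.0175. Prss23os fell by 1.37 (adjusted p = 0.0175). It is annotated as antisense, and since the sources do not say how strand was used in counting, its identity is uncertain. Nefh (ENSMUSG00000020396) lies on chromosome 11 from 4938754 to 4948064, Esrra (ENSMUSG00000024955) on chromosome 19 from 6910977 to 6921813, and Polr3b (ENSMUSG00000034453) on chromosome 10 from 84622292 to 84727178.

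The pituitary hormone genes Cga and Pomc also passed the test, at -8.12 ± 1.59 (adjusted p = 0.0175) and -5.02 ± 1.06 (adjusted p = 0.0181). Without saline replicates 2 and 3, Cga was at -1.69 (adjusted p = 0.279) and Pomc at 0.04 (adjusted p = 0.958). The genes of the 2 targets gave 0.15 ± 0.07 for Dlg4 (adjusted p = 0.129) and 0.15 ± 0.07 for Pick1 (adjusted p = 0.155). The appetite neuropeptide genes Agrp (0.40 ± 0.34), Npy (0.31 ± 0.20) and Cartpt (0.26 ± 0.15) had adjusted p of 0.449, 0.309 and 0.243. Agrp and Npy were above the saline median in 7 of 8 PICK1i libraries and Cartpt in 5. PICK1i replicate 6 held the least Agrp, 0.21 CPM, and also stood apart in markers of hypothalamic nuclei and of cortex, given below.

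Of 39 gene lists, 16 stood apart from the other genes by camera with a preset correlation of 0.01, 10 toward higher and 6 toward lower values (18 at an unadjusted p under 0.05). With an estimated correlation 0 were called, and 8 passed fry. For comparison with the counts below, 1434 of all 15667 genes passed. Of 74 nuclear-encoded oxidative phosphorylation genes 45 rose and 0 fell, 63 when adjusted over the list alone, with Ndufs7 (0.51) and Cox7b (0.39) among them. By fry this list had adjusted p = 0.0154. Of 15 mitochondrially encoded genes 8 rose, 13 when adjusted over the list alone, mt-Nd2 by 0.51 and mt-Nd4 by 0.45. For this list camera gave adjusted p = 7.47e-08, and adjusted p = 0.511 with an estimated correlation. Both lists were highest in PICK1i replicates 1, 2, 5 and 6, whose mitochondrial share was at least 13.47%. Without those 4 libraries camera gave adjusted p = 4.84e-10 for the nuclear-encoded list (adjusted p = 0.557 with an estimated correlation) and 0.102 for the mitochondrially encoded one. The other 4 PICK1i libraries had means of the nuclear-encoded list of -0.0767 to 0.0569. Saline replicates 2 and 3 had the lowest means, -0.225 and -0.301, against -0.154 to 0.00835 in the other saline libraries. Of 31 proteasome genes 5 rose, 13 when adjusted over the list alone, led by Psmc5 (0.32) and Psmb5 (0.32). The proteasome list had adjusted p = 1.83e-06, and adjusted p = 0.511 with an estimated correlation. Of 24 heat shock and chaperone genes 5 rose, among them Hspa8 (0.20) and Ahsa1 (0.18), and 6 rose and 2 fell when adjusted over the list alone. The chaperone list had adjusted p = 0.033, and adjusted p = 0.511 with an estimated correlation.

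Myelin and mature oligodendrocyte genes were higher, with 3 of 24 past the test, Nkx6-2 (0.37), Bcas1 (0.65) and Mobp (0.52), and 6 when adjusted over the list alone. The myelin list had adjusted p = 5.32e-06, adjusted p = 0.637 with an estimated correlation, and 0.0646 without saline replicates 2 and 3. In the oligodendrocyte precursor list 1 of 13 genes rose, also 1 when adjusted over the list alone, the proteoglycan gene Cspg5 by 0.38 (adjusted p = 0.0147, and adjusted p = 0.658 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 1 rose, Rps15 by 0.27, and 0 when adjusted over the list alone (adjusted p = 0.000375, and adjusted p = 0.772 with an estimated correlation). The ribosomal list turned to lower values without PICK1i replicates 1, 2, 5 and 6 (adjusted p = 3.23e-07) and with length tilt as a covariate (1.9e-09). Among immediate early genes, which neurons induce on activation, Arc (0.77) and Egr4 (0.55) rose, 2 of 28 and also 2 when adjusted over the list alone. Immediate early genes as a list had adjusted p = 0.0271, and adjusted p = 0.736 with an estimated correlation. Of 23 glucocorticoid-responsive genes 2 rose, Cdkn1a (0.40) and Plin4 (0.76), and 6 when adjusted over the list alone (adjusted p = 0.0461, and adjusted p = 0.772 with an estimated correlation). Of 10 appetite-raising neuropeptide genes 1 rose, the enkephalin precursor Penk by 0.39, and also 1 when adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.637 with an estimated correlation).

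Toward lower values, 5 of 21 tanycyte genes fell, 6 when adjusted over the list alone, among them Deptor (-0.54), Fgf10 (-0.66) and Mest (-1.54). Tanycytes are the glial cells that line the floor of the third ventricle, and their list had adjusted p = 0.0013, and adjusted p = 0.511 with an estimated correlation. Its mean deviation was lowest in PICK1i replicates 5 and 6, at -0.46 and -0.728, against -0.105 to -0.00989 in the other 6, and replicate 6 also stood apart in markers of cortex and hippocampus (1.5), neuroendocrine nuclei (-0.763) and ependyma (-0.9). In the list of energy balance receptors and signalling Foxo1 (-0.59), the leptin signal mediator Stat3 (-0.35) and the insulin receptor gene Insr (-0.22) fell, 3 of 36. When adjusted over the list alone 4 fell, and the list had adjusted p = 0.0129, and adjusted p = 0.511 with an estimated correlation. Of 20 clock genes 3 fell, among them Cry2 (-0.23) and Per3 (-0.40), also 3 when adjusted over the list alone (adjusted p = 0.00815, and adjusted p = 0.511 with an estimated correlation). The leptomeningeal matrix genes Lum (-1.52) and Dcn (-1.36) fell, 2 of 21, also 2 when adjusted over the list alone (adjusted p = 0.00815, and adjusted p = 0.772 with an estimated correlation). The interferon response genes Ifih1 (-0.80) and Gbp7 (-0.92) fell, 2 of 29, also 2 when adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.772 with an estimated correlation). In the reactive astrocyte list Fabp7 rose by 0.69 while Emp1 (-1.43) and Cd109 (-0.62) fell, 3 of 19 in all. When adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.0227, and adjusted p = 0.577 with an estimated correlation). Median, mean and test had the same sign in each of the 16 lists. Without saline replicates 2 and 3, camera gave adjusted p = 0.00196 for tanycytes, 0.000619 for energy balance, 0.111 for the clock, 0.0349 for leptomeninges, 0.326 for interferon, 0.547 for oligodendrocyte precursors and 0.361 for appetite-raising neuropeptides. With an estimated correlation 0 lists were called there, and 0 without the 4 PICK1i libraries. Without PICK1i replicates 1, 2, 5 and 6 it gave 0.71 for energy balance, 0.0851 for the clock, 0.119 for immediate early genes and 0.119 for appetite-raising neuropeptides. With 1 library left out in turn, the chaperone (adjusted p up to 0.131), glucocorticoid (0.205) and appetite-raising lists (0.104) stayed called in 11 of 16 fits, immediate early (0.0861) and interferon genes (0.0892) in 13, and oligodendrocyte precursors (0.0909) and reactive astrocytes (0.106) in 14. The leptomeningeal list stayed in 14 as well (0.134, without saline replicate 7), the ribosomal list in 15 (0.0751), and the other 7 in all 16.

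The called genes also differed in transcript length, with a median of 957 bases for higher genes and 2144 bases for lower genes against 1511 for all tested. The count of 1434 genes was 702, 819, 299, 539 and 2757 without PICK1i replicate 1, 2, 5, 6 or 7, and 404, 633 and 879 without saline replicate 2, 3 or 4. It was 5 without saline replicates 2 and 3 together, 0 without PICK1i replicates 1, 2, 5 and 6, 0 (edgeR) when only the 2 groups were fitted, 129 with 2 surrogate variables, 65 with length tilt as a covariate (11 higher and 54 lower), 316 with consecutive libraries as a random block in limma-voom, 3 by limma-voom with sample weights, 1114 by limma-voom without them and 1991 by DESeq2. Without PICK1i replicates 1, 2, 5 and 6 all 1434 genes kept their sign, with a median log2 fold change in the direction of the call of 0.19 against 0.34. The genes were chosen from data that include the remaining libraries, so kept signs are no separate support. Without these PICK1i libraries Esrra was at 0.38, Nefh at 0.39, Polr3b at -0.36, Ndufs5 at 0.20 and Cox5b at 0.22, with adjusted p of 0.13, 0.114, 0.367, 0.367 and 0.367.

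**Figure D2:**
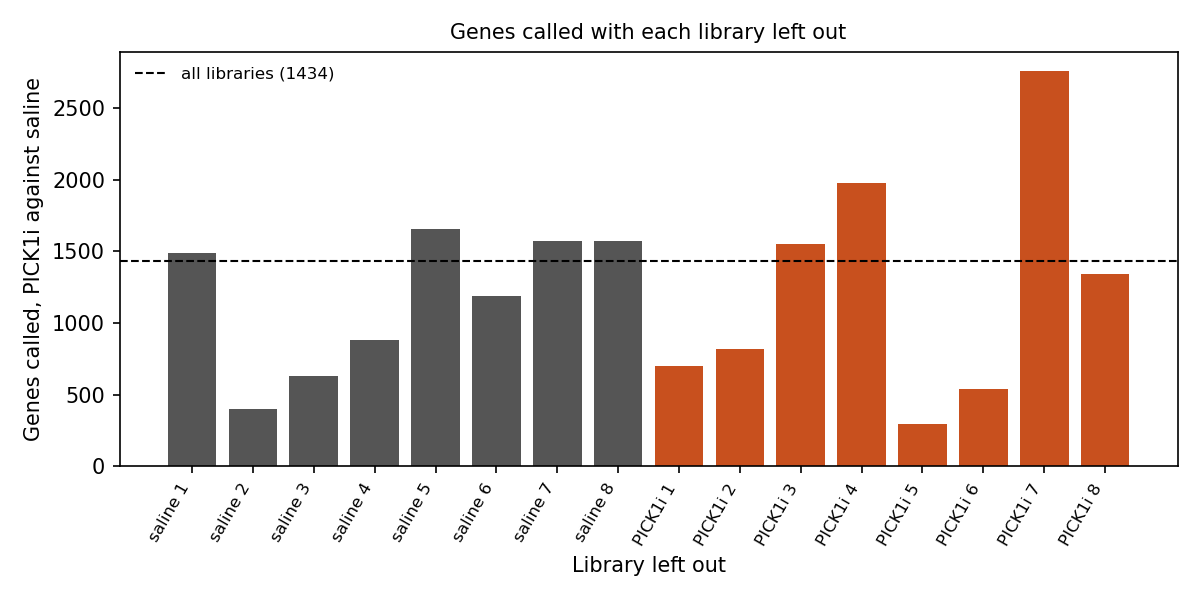
Number of genes past an adjusted p of 0.05 for PICK1i against saline (vertical axis, genes) when each of the 16 libraries was left out in turn (bars, grey for saline and orange for PICK1i), with a dashed line at the 1434 genes of all libraries. The count ran from 299 without PICK1i 5 to 2757 without PICK1i 7.

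The comparison of PSD-95i with saline asked which transcripts differ after PSD-95 inhibition. As a group, genes of red blood cells were lower in PSD-95i, with a median log2 fold change of -1.34 over 8 genes. Values were -1.50 ± 0.41 for the alpha globin gene Hba-a2 and -1.60 ± 0.44 for Alas2, the enzyme of the opening step of haem synthesis in red cells. Of the 8 genes 5 fell when adjusted over the list alone, and camera gave adjusted p = 9.56e-06, against adjusted p = 0.634 with an estimated correlation. The mean deviation of this list varied widely and overlapped between the groups, from -0.47 to 0.964 in saline libraries and from -0.879 to 0.479 in PSD-95i libraries. Leptomeningeal fibroblast genes had a median of -0.46 over 21 genes, all 21 below 0, with Dcn at -1.03 and Col3a1 at -1.18. Saline replicate 7 had the highest mean of this list, 1.93 above the mean of all libraries, and without it the list had adjusted p = 0.187. None of them passed when adjusted over the list alone (0 of 21, camera adjusted p = 0.00116, and adjusted p = 0.634 with an estimated correlation). Cholesterol synthesis and uptake genes had a median of 0.09, with 24 of 25 above 0 and Mvk at 0.29, and 0 passed when adjusted over the list alone (adjusted p = 2.94e-05, and adjusted p = 0.634 with an estimated correlation).

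No single gene passed the threshold by edgeR (0 of 15667, 1719 at an unadjusted p under 0.05, smallest adjusted p 0.286), and DESeq2 and limma-voom also gave 0. The genes with the smallest p included Cga (-7.91 ± 1.54), Pomc (-5.12 ± 1.07) and the pituitary list gene Oacyl (-4.66 ± 1.02). The keratin gene Krt8 (-3.14), the pituitary transcription factor gene Lhx3 (-3.75), S100a11 (-1.64), Fam46c (-1.38), Airn (-0.87), an antisense transcript of uncertain strand assignment, and Krcc1 (-0.65) followed, all with adjusted p = 0.286. Without saline replicates 2 and 3 the values were -1.45 for Cga, -0.05 for Pomc, 0.12 for Oacyl, -0.51 for Krt8, 0.12 for Lhx3, -0.65 for S100a11, -0.74 for Fam46c, -0.70 for Airn and -0.36 for Krcc1, each with adjusted p = 1. Nefh was at 0.29 ± 0.07, above the saline median in 8 of 8 libraries, with adjusted p = 0.286. Dlg4 was at 0.11 ± 0.07 (adjusted p = 0.54) and Pick1 at -0.07 ± 0.07 (adjusted p = 0.705). Agrp was at 0.15 ± 0.34, Npy at 0.07 ± 0.20 and Cartpt at 0.10 ± 0.15, with adjusted p of 0.893, 0.921 and 0.817.

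By camera, 19 of 39 lists were called, 10 toward higher and 9 toward lower values (21 at an unadjusted p under 0.05). With an estimated correlation 0 were called, each of the 19 having adjusted p = 0.634 with an estimated correlation, and 0 were called by fry. Synaptic lists were on the higher side, with medians of 0.10 for AMPA and kainate receptors and PICK1 partners (adjusted p = 0.000561), 0.08 for postsynaptic density scaffolds (adjusted p = 0.000581), 0.11 for NMDA receptor subunits and MAGUKs (adjusted p = 0.0465), 0.14 for presynaptic vesicle release (adjusted p = 2.01e-05) and 0.14 for GABA signalling (adjusted p = 1.58e-05), each with adjusted p = 0.634 with an estimated correlation. Without saline replicates 2 and 3 these gave 0.885, 0.987, 0.982, 0.0983 and 0.107. Astrocyte (median 0.14, adjusted p = 7.25e-06), oligodendrocyte precursor (0.15, adjusted p = 0.000186), myelin (0.12, adjusted p = 0.00102) and nuclear-encoded oxidative phosphorylation genes (0.07, adjusted p = 3.26e-05) were also higher as lists. Each had adjusted p = 0.634 with an estimated correlation, and without those 2 libraries none of these 4 stayed called. The myelin list turned to lower values with 2 surrogate variables (adjusted p = 0.000287) and without these 2 and PICK1i replicates 1, 2, 5 and 6 (0.0421). On the lower side were cytosolic ribosomal proteins (median -0.11, adjusted p = 9.54e-07), interferon response (-0.23, adjusted p = 0.0102), endoplasmic reticulum stress (-0.09, adjusted p = 0.0168), pituitary (-0.91, adjusted p = 0.0266), tanycyte (-0.10, adjusted p = 0.0273), inflammatory signalling (-0.17, adjusted p = 0.0383) and reactive astrocyte genes (-0.07, adjusted p = 0.0383). Each of these had adjusted p = 0.634 with an estimated correlation. When adjusted over the list alone, 5 pituitary and 2 reactive astrocyte genes fell, and 0 genes passed in the other called lists apart from the red blood cell list. Of all 19 called lists, red blood cell (1.59e-09), leptomeningeal (0.00393), cholesterol (0.0103), tanycyte (0.0286) and reactive astrocyte (0.0177) stayed called without saline replicates 2 and 3. With an estimated correlation they had adjusted p = 0.217, 0.919, 0.607, 0.809 and 0.809 there, and 0 lists were called. With 1 library left out in turn, the NMDA receptor list stayed called in 7 of 16 fits (adjusted p up to 0.295), reactive astrocyte in 8 (0.153), inflammatory signalling in 9 (0.143), tanycyte in 10 (0.195) and interferon in 12 (0.109). Endoplasmic reticulum stress (0.2) and pituitary (0.217) stayed in 14, leptomeningeal (0.187), myelin (0.285) and postsynaptic density (0.102) in 15, and the other 9 in all 16. In the test on simulated data, 91.4% of genes changed 2-fold, 68.9% changed 1.5-fold and 23.9% with a log2 change of 0.32 were called in this comparison, so small changes were mostly not detectable.

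The comparison of PSD-95i with PICK1i asked whether the inhibitors differ from each other, at doses of 25 and 56 mg/kg that are not matched. Mitochondrial genes were lower as groups in PSD-95i than in PICK1i. Nuclear-encoded oxidative phosphorylation genes had a median of -0.26 over 74 genes, with Cox7b at -0.34 ± 0.08 and Ndufs5 at -0.36 ± 0.09. When adjusted over the list alone 49 fell and 1 rose (camera adjusted p = 1.3e-19, adjusted p = 0.669 with an estimated correlation). Mitochondrially encoded genes had a median of -0.40, and 15 of 15 fell when adjusted over the list alone, mt-Nd4 by 0.50 ± 0.11 (adjusted p = 2.42e-10, adjusted p = 0.669 with an estimated correlation, fry adjusted p = 0.0463). Immediate early genes had a median of -0.25, and 4 of 28 fell when adjusted over the list alone. These were Egr2 (-1.74 ± 0.47), Arc (-0.80 ± 0.22), Gadd45g (-0.38 ± 0.10) and Ier5 (-0.42 ± 0.12) (list adjusted p = 0.000253, adjusted p = 0.669 with an estimated correlation).

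Cytosolic ribosomal protein genes (median -0.22, 35 of 78 lower when adjusted over the list alone, adjusted p = 4e-16), proteasome genes (-0.14, 9 lower and 1 higher of 31, adjusted p = 3e-04) and red blood cell genes (-1.0, 6 lower and 1 higher of 8, adjusted p = 0.0167) were lower too, each with adjusted p = 0.747 with an estimated correlation. With length tilt as a covariate the ribosomal list turned to higher values (adjusted p = 4.88e-12). Myelin genes had a median of -0.12 and 0 of 24 past the test when adjusted over the list alone (adjusted p = 0.0248, adjusted p = 0.87 with an estimated correlation). Energy balance receptors and signalling were higher in PSD-95i, with 6 of 36 higher when adjusted over the list alone, among them Glp1r at 1.15 and Ntrk2 at 0.32. Their median was 0.15 (adjusted p = 0.000814, adjusted p = 0.669 with an estimated correlation, fry adjusted p = 0.0463). GABA signalling genes were higher as well (median 0.17, 2 higher and 1 lower of 22 when adjusted over the list alone, adjusted p = 4e-04). So were cholesterol genes (0.08, 5 of 25 higher when adjusted over the list alone, adjusted p = 0.0292). Both had adjusted p = 0.754 with an estimated correlation. Of the 10 lists called, 3 toward higher and 7 toward lower values (13 at an unadjusted p under 0.05), 0 were called with an estimated correlation and 2 by fry. Without PICK1i replicates 1, 2, 5 and 6, which had the largest mitochondrial share, the lists of oxidative phosphorylation (0.00406), mitochondrially encoded (0.00617), immediate early (5.38e-05) and red blood cell genes (0.00355) stayed called, while the other 6 gave 0.204 to 0.983. With an estimated correlation 0 lists were called there, and these 4 had adjusted p = 0.994, 0.994, 0.977 and 0.994. With 1 library left out in turn, the myelin list stayed called in 14 of 16 fits (adjusted p up to 0.106), the cholesterol list in 15 (0.0662) and the other 8 in all 16.

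No gene passed by edgeR (0 of 15667, 3789 at an unadjusted p under 0.05), and 1359 passed by DESeq2, 429 by limma-voom, 436 by limma-voom with sample weights and 1539 with 2 surrogate variables. With consecutive libraries as a random block in limma-voom 0 passed. By edgeR the smallest adjusted p was 0.0513. On the higher side it was shared by Gpr107 (0.28 ± 0.05), Lancl2 (0.41 ± 0.08), Fam120c (0.68 ± 0.14), Ldoc1l (0.37 ± 0.08), Ikbkap (0.39 ± 0.08), Klhl24 (0.36 ± 0.07) and Polr3b (0.37 ± 0.08). On the lower side it was shared by Zcrb1 (-0.38 ± 0.07), Cacybp (-0.25 ± 0.05) and Esrra (-0.35 ± 0.07). Each of these 10 had 8 of 8 libraries on the same side of the PICK1i median. Pick1 was at -0.23 ± 0.07 (adjusted p = 0.0679) and Dlg4 at -0.05 ± 0.07 (adjusted p = 0.717). Pomc (-0.09 ± 0.92), Agrp (-0.25 ± 0.33), Npy (-0.24 ± 0.20) and Cartpt (-0.16 ± 0.15) had adjusted p of 0.966, 0.687, 0.477 and 0.534. The count of 0 was 756, 1420, 2315 and 379 without PICK1i replicate 3, 4, 7 or 8, 1 without PSD-95i replicate 2, and 1208 without saline replicates 2 and 3, which are in neither group but share the filter, the scaling and the estimate of spread.

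The log2 fold changes of the inhibitors against saline had a correlation of 0.691 across the 15667 genes, which are not independent replicates, and a covariance of 0.0511. Esrra and Nefh, for example, were at 0.47 and 0.42 in PICK1i, and Nefh at 0.29 in PSD-95i. Both comparisons use the same saline libraries, and 20 simulated pairs of unchanged groups gave a mean correlation of 0.50 (0.477 to 0.524) and a covariance of 0.0162. With separate saline libraries for each inhibitor, 4 each over 70 assignments, the mean correlation was 0.312, ranging from -0.076 to 0.589, with a mean covariance of 0.0254. Without saline replicates 2 and 3 the correlation was 0.393 with a covariance of 0.0139, without PICK1i replicates 1, 2, 5 and 6 it was 0.854 with 0.0986, and without all 6 it was 0.599 with 0.0206. No gene was called in both inhibitors, and 0 were expected, since PSD-95i had 0 calls by edgeR (1719 at an unadjusted p under 0.05) and by DESeq2.

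At the level of transcripts, 371 were higher and 389 lower in PICK1i than in saline, 760 of 37955 tested by edgeR, and they belonged to 686 genes. For 621 of the 760 the gene itself was called. The smallest p belonged to transcripts of Esrra (0.46 ± 0.07), Nefh (0.41 ± 0.07) and Uncx (0.87 ± 0.14), each with adjusted p = 0.0159. The count of transcripts was 19 with the replicate number as a block, 0 without saline replicates 2 and 3 and 0 without PICK1i replicates 1, 2, 5 and 6. For PSD-95i, 0 transcripts passed by edgeR against saline (2768 at an unadjusted p under 0.05, smallest adjusted p 0.232). Against PICK1i edgeR also gave 0 (8092 at an unadjusted p under 0.05, smallest adjusted p 0.0686). No other tool was run on transcripts.

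**Figure D3:**
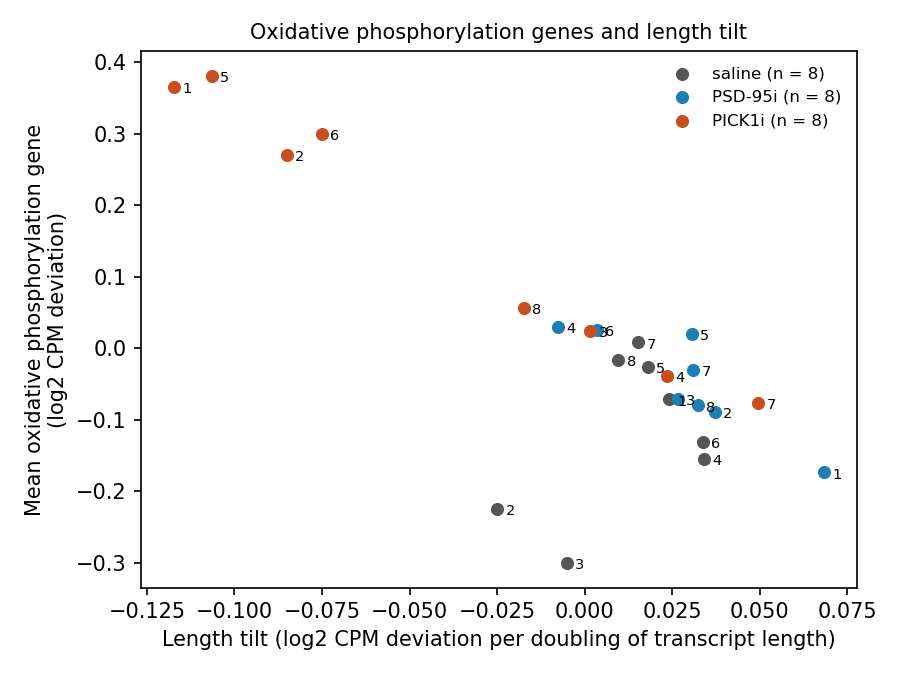
Mean log2 CPM deviation of 74 nuclear-encoded oxidative phosphorylation genes (vertical axis) against length tilt, the slope of a library's log2 CPM deviations on log2 transcript length over the other genes (horizontal axis), for 8 libraries per group. PICK1i 1, 2, 5 and 6 lie at the upper left, and saline 2 and 3 lie below the other libraries.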

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

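The rule for a library far from its group was fixed beforehand, while the library measures and lists it was applied to were chosen after the data were seen. A library was taken as far from its group when its gap to the nearest of the other 7, divided by the range of the group, exceeded Dixon's 95% limit for 8 values. All 39 gene lists, 4 library measures and the named genes were examined. The rule was met in 20 of 261 groups of values, against 13 by chance at 1 in 20. No explanation was weighed for single libraries.

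Pomc and Agrp were far lower in PICK1i 6 than in its group, at 3.08 log2 CPM (nearest 6.48) and -1.01 log2 CPM (nearest 1.84). Against the mean of all libraries on the log2 scale, the same library was lowest of its group for neuroendocrine and nucleus markers, at -0.763 (nearest -0.0324), and for ependymal genes, at -0.9 (nearest -0.134). It was highest for cortex and hippocampus markers, at 1.5 (nearest 0.0474). It also had the highest mean of postsynaptic density scaffolds, 0.341, and the highest mean of red blood cell genes, 1.6. Red blood cell genes were also highest for their group in PSD-95i 6, at 0.479 (nearest -0.349). In saline 7 the means of endothelial genes, 0.47 (nearest 0.00772), mural cell and smooth muscle genes, 0.728 (nearest 0.0505), and choroid plexus genes, 0.521 (nearest 0.138), were the highest of the saline group. Ependymal genes were lowest in saline 2, at -0.38 (nearest -0.000176). Astrocyte genes had the lowest PICK1i mean in PICK1i 1, at -0.173 (nearest -0.018). In PICK1i 8 the pituitary list had the highest mean of its group, 0.291 (nearest -0.344), and Cga stood at 3.25 log2 CPM (nearest -1.01). Pick1 was highest among saline libraries in saline 3, at 6.26 log2 CPM (nearest 6.05). Kat2a was lowest among saline libraries in saline 2, at 5.91 log2 CPM (nearest 6.05), and Atad3a lowest among PSD-95i libraries in PSD-95i 1, at 5.14 log2 CPM (nearest 5.28). The mitochondrially encoded share was lowest among saline libraries in saline 2, at 7.88% (95% Wilson interval 7.86 to 7.90%, nearest 9.60%). The fewest genes of the saline group were detected in saline 6, 20848 against at least 21430. PICK1i 6 met the rule 7 times, saline 2 and saline 7 each 3 times and PICK1i 8 met it 2 times.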

How the results depend on the processing

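The settings without saline 2 and 3, without PICK1i 1, 2, 5 and 6, without all 6, with the length and GC offset and with length tilt as a covariate were chosen after the data were seen. For PICK1i against saline, the count of 1434 genes stayed within 1.5 times under RLE (1436), no filter (1050), a stricter filter (1440), the replicate block (1127), library number (1524), DESeq2 (1991), limma-voom (1114) and the offset (1043, 663 higher and 380 lower). It was 129 with 2 surrogate variables, 65 with length tilt (11 higher and 54 lower), 316 with consecutive libraries as a random block, 3 with sample weights and 0 by edgeR with only the 2 groups fitted. It was 5 without saline 2 and 3 (3839 at an unadjusted p under 0.05), 0 without PICK1i 1, 2, 5 and 6 (1961, with 1434 of the 1434 genes keeping their sign and a median signed fold of 0.194 against 0.344) and 0 without all 6 (1325). Kept signs are no separate support, as the genes were chosen from data that include the remaining libraries. Leaving out 1 library gave 299 to 2757, and choosing 6 of 8 saline libraries gave 0 at the fewest, a median of 887.5 and 1934 at the most. Choices that left out saline 2 or 3 gave 0 to 556 genes, and choices that kept both gave 792 to 1934. Transcripts numbered 19 with the replicate block and 0, 0 and 0 without the 2, 4 or 6 libraries. PSD-95i against saline stayed at 0 genes in every setting but 6 of 8 saline libraries, with a median of 2 and at most 83. In that setting it was 0 in each choice that left out saline 2 or 3. PSD-95i against PICK1i gave 1539 genes with 2 surrogate variables, 1359 by DESeq2, 429 by limma-voom, 436 with sample weights, 0 with consecutive libraries as a random block in limma-voom, 1208 without saline 2 and 3, 0 to 2315 with 1 library left out, 5 without saline 3 and 4, and 0 by edgeR elsewhere. Called lists for PSD-95i against saline, PICK1i against saline and PSD-95i against PICK1i numbered 0, 0 and 0 with an estimated correlation and 0, 8 and 2 by fry. With 1 library left out they ran from 14 to 23, 11 to 20 and 9 to 14. PSD-95i against saline had 6 lists with 2 surrogate variables and 10 without saline 2 and 3. The correlation was 0.312 with split saline libraries, 0.393 without saline 2 and 3, 0.854 without PICK1i 1, 2, 5 and 6, 0.599 without all 6, and 0.629 with the replicate block. Replicate numbers were not found to pair libraries, since deviations of libraries with 1 number correlated above 0.1 in 2, 3 and 0 of 8 pairs. The block costs degrees of freedom, and whether these numbers mark a shared source was not settled.

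Signs turned for the myelin list of PSD-95i against saline (lower, adjusted p = 0.000287 with 2 surrogate variables and 0.0421 without all 6 libraries). They also turned for the ribosomal list of PICK1i against saline (lower, 3.23e-07 without PICK1i 1, 2, 5 and 6, 0.0224 without all 6, 1.9e-09 with length tilt) and of PSD-95i against PICK1i (higher, 4.88e-12 with length tilt), and for Pomc in PICK1i (log2 fold changes of 0.0077 with 2 surrogate variables, 0.037 by DESeq2 and 0.040 without saline 2 and 3). Of the 25 named genes called for PICK1i, all 25 stayed called with each library left out, 24 with the replicate block, 3 without saline 2 and 3 (Nefh, Esrra and Ndufaf6), 3 with sample weights and 0 without PICK1i 1, 2, 5 and 6. With 2 surrogate variables 20 stayed called, and with length tilt as a covariate 12. With only the 2 groups fitted, 0 of the 24 compared stayed called. Of 1080 values of called lists under alternatives, 913 kept the call, 161 lost it and 6 turned, while an estimated correlation, not among them, ended all 45 calls. Signs of fold changes that passed no threshold in either fit were not compared. Apart from the smaller number of libraries where some were left out, the cause was not tested. A filter at 1 CPM removed no gene (15667 of 15667) and says nothing.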

Other observations

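The tests of the length and GC offset, of leaving out saline replicates 2 and 3 and PICK1i replicates 1, 2, 5 and 6, of pituitary and hypothalamic markers and of consecutive library numbers were chosen only after the result was seen. Several genes of the synapse passed the test in PICK1i against saline although their lists did not. Over all genes 1434 of 15667 passed, and the shares in the synaptic lists, from 1 of 22 to 4 of 30, lay on both sides of that. Of 30 genes of presynaptic vesicle release 4 rose, and 5 rose and 1 fell when adjusted over the list alone. The 4 were Rab3a (0.37), Snap25 (0.32), Unc13a (0.23) and Syp (0.23) (camera adjusted p = 0.221). Among AMPA and kainate receptors and PICK1 partners, the auxiliary subunit genes Shisa7 (0.34) and Cacng7 (0.26) rose and the kainate receptor gene Grik3 (-0.37) fell, 3 of 27 (adjusted p = 0.341). The scaffold gene Begain (0.33) and the kinase gene Cit (0.27) rose, 2 of 38 genes of the postsynaptic density (adjusted p = 0.221). The GABA receptor subunit gene Gabra2 rose by 0.31, 1 of 22 (adjusted p = 0.695).

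In blood vessels, the endothelial genes Pglyrp1 (0.73) and Ly6c1 (0.48) rose in PICK1i while the VEGF receptor gene Kdr (-0.69) fell, 3 of 22 (adjusted p = 0.282). The endoplasmic reticulum stress genes Dnajc3 (-0.49), Crebrf (-0.27) and Dnajb9 (-0.36) fell, 3 of 31 (adjusted p = 0.184), and the p53 target genes Phlda3 (0.42) and Cdkn1a (0.40) rose, 2 of 19 (adjusted p = 0.899). Of 24 microglia genes 1 fell, Sall1 by 0.28 (adjusted p = 0.282), and without saline replicates 2 and 3 the list was lower in both PICK1i (adjusted p = 0.000555, and adjusted p = 0.571 with an estimated correlation) and PSD-95i (2.83e-05, and adjusted p = 0.551 with an estimated correlation). Of 8 red blood cell genes 1 rose and 1 fell, the latter Fech (-0.20) (adjusted p = 0.606). In PICK1i against saline the markers of neighbouring brain regions had adjusted p of 0.661 for thalamus, 0.547 for striatum and 0.221 for cortex and hippocampus. Of 8 tested pituitary genes 5 fell (adjusted p = 0.0845). In PICK1i 6 the cortical glutamate transporter gene Slc17a7 stood at 248 CPM and Avp at 87.4 CPM, while the saline means were 16.1 and 317 CPM.

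Splits of the same libraries into other groups of 8, with 100 drawn per comparison and the real split among them, were compared with the real result. For PICK1i against saline, 2 of 100 splits gave as many genes as the real 1434 (highest other 1475), and 2 gave as many transcripts as the real 760 (highest other 5437). Such counts were rare among splits of single libraries, which does not exclude chance. The split that exchanged only PICK1i 8 and saline 4 gave 0 genes, so the count depends strongly on single libraries. The split with 1475 genes and 5437 transcripts exchanged PICK1i 3 and 7 for saline 3 and 8 and kept PICK1i 1, 2, 5 and 6 together, which points to a structure of the samples around those 4 libraries. They form 2 pairs of consecutive numbers, which these splits ignore. All 35 splits that keep consecutive numbers together were added after the data were seen. Of them 1, the real one, gave as many genes as 1434 (highest other 1257), and 3 gave as many transcripts as the real 760 (highest other 1809). By pairs the share for the genes was 0.0286, the lowest that 35 splits can give. Other splits with PICK1i 1, 2, 5 and 6 in one group and saline 1 to 4 in the other gave 1257, 1080, 670, 435 and 0 genes. The remaining splits gave at most 513. The count thus followed where these libraries fell, so the splits by pairs leave chance open for the genes and for the transcripts. Chance could not be excluded for the number of called lists. For PSD-95i against saline 25 of 100 splits gave as many as the real 19 (highest other 24), 43 gave as many as the real 16 for PICK1i against saline (highest other 26), and 68 gave as many as the real 10 for PSD-95i against PICK1i (highest other 20). Nor could it be excluded for the correlation of 0.691, which 28 of 100 splits into 3 groups matched (highest other 0.869). For counts of 0 the splits decide nothing, since every split gives at least 0. This holds for genes in PSD-95i against saline and against PICK1i (0 and 0 by edgeR, 1719 and 3789 at an unadjusted p under 0.05, highest other 0 and 0) and for transcripts (0 and 0 by edgeR, highest other 0 and 1711).

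Of 3 technical explanations tested for the 1434 genes called in PICK1i, a smooth trend with transcript length and GC content as the whole cause is argued against, since 799 stayed called with an offset for it, although with length tilt as a covariate 58 stayed called at a median signed fold of 0.25 (quartiles 0.173 and 0.395). Pituitary tissue in saline replicates 2 and 3 as the whole cause is not settled. Without them the median fold in the direction of the call was 0.27 (quartiles 0.209 and 0.366) against 0.344 (0.27 and 0.481). The genes were chosen from data that include the remaining libraries, so folds in the same direction cannot decide it. Only 5 genes were called with the smaller folds and 6 saline libraries, while 3839 of 15820 had an unadjusted p under 0.05. Other choices of 6 saline libraries gave 792 to 1934 genes where saline replicates 2 and 3 were both kept. They gave 0 to 556 where 1 of these 2 was left out. A library quality factor that moves short transcripts and oxidative phosphorylation genes together may contribute, because length tilt and the mean of those genes were correlated within PSD-95i (r = -0.874, exact permutation p = 0.00293, adjusted p = 0.00439 over 3 relations, rho = -0.929, p = 0.00223, but r = -0.655, p = 0.0889 without the 2 farthest) and within PICK1i (r = -0.989, p = 0.000124, rho = -0.952, p = 0.00114, and r = -0.99, p = 0.00556 without the 2 farthest). Within saline r was 0.474 (exact permutation p = 0.237, rho = 0.167, p = 0.703), on the side of 0 written beforehand as evidence against the factor, and it was read as open only once the value was known, because p exceeds 0.05 and r was -0.946 (p = 0.00833) without the 2 farthest, saline 2 and 3. An effect of PICK1 inhibition that was larger in 4 of the 8 mice could give the relation within PICK1i, though not the one within PSD-95i. Such an effect remains open, as no measure of RNA quality is given.

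Pituitary transcripts in saline replicates 2 and 3 could come from pituitary tissue in those dissections. Pomc, which is outside the pituitary list, stood at 13910 and 16810 CPM there. Of 18 pituitary list genes, 16 were higher in both than in each of the other 22 libraries, led by Gh (52240 and 31690 CPM) and Prl (7954 and 4871 CPM). The exceptions were Trhr and Pcsk1n, and hypothalamus also expresses some of the 18, with medians in the other 22 libraries of 1445 CPM for Pcsk1n, 488 CPM for Chgb and 380 CPM for Dlk1. A pituitary library in place of a hypothalamic one is argued against, because the lower of the 2 median ratios over 26 neuroendocrine and nucleus markers was 0.708. No biological explanation was tested, since the design has no group of pituitary samples.

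Libraries with consecutive numbers, 12 pairs of which each lie in 1 group, had a mean correlation of deviations of -0.0242, against -0.133 for random pairs within groups (one-sided permutation test, 100000 resamples, p = 0.085). Shared handling or housing may therefore contribute and stays open, as the labels do not say what the numbers mean. The mean of -0.0242 includes the 2 lowest pairs, saline 1 with 2 (-0.599) and saline 3 with 4 (-0.298), which hold saline 2 and 3. Of the 12 pairs, 7 were above 0. A random block for these pairs in limma-voom estimated a correlation of 0.141 within them. It left 316 genes called for PICK1i, against 1114 without it.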
